A study of Homo sapiens with 6 samples.

How the data were processed

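RNA from NALM6 cells with a hairpin against PRMT5 or against luciferase was hybridised to single-colour human arrays, 3 per group and 6 in all. Per the labels, total RNA was amplified and labelled indirectly with Cy5, and the Cy3 signal of the manufacturer's control probes was left out of processing. Groups and replicate numbers came from the sample titles. The values deposited by the authors were probe intensity on a linear scale, with 29187 probes. Between 2.42 and 4.11% of values per array were at or below 0, which shows that background had been subtracted. All values of an array (100%, within 0.05 of a step) were whole multiples of 1 step, between 0.803 and 1.07, so that at most a linear factor per array had been applied. The scanner, its software, the background method and any scaling were not given in the sources used here. Background could not be redone, since no scanner columns were used here. There were 0 other columns of values per sample. The labels give no slide, scan or batch, and do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

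Values at or below 0 were set to the lowest positive value of the table (0.803) and log2-transformed. The rule set beforehand was to normalize only if array medians differed by over 0.5 log2. They differed by 0.738, and quantile normalization was applied (limma 3.58.1 in R 4.3.3). This makes array distributions equal, so a change in the same direction in most genes would be removed. Differences of dim probes depend on the floor and on the subtracted background. A platform annotation table gave 25053 probes 1 gene symbol, 0 probes several and 4134 none. The gene identifiers of 24981 probes were found in a reference table of gene names, where 0 symbols differed. A gene was represented by its probe with the highest mean over all 6 arrays, which gave 18821 genes. Probes and genes were tested with lmFit and eBayes (no trend, not robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. No probe was filtered in the tests reported. Bright genes are those with a mean above the median of all genes.

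Lists of genes for 28 pathways, complexes and cell types were fixed before the data were examined, with 585 entries and 576 different genes, of which 518 were measured. They covered the PRMT5 complex and other arginine methyltransferases, B-cell stages, markers of other blood and tissue cell types, the cell cycle, p53, apoptosis, splicing, stress responses, interferon and NF-kB, metabolism, ribosomes, lysosomes, DNA repair, reference genes and histones. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and members were also adjusted over the list alone. Camera with an estimated correlation called 0 lists and fry called 0.

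The rule for named genes was also fixed beforehand. It took up to 12 genes per direction past the test with separated groups and a mean above the median. Where none passed, it took the 8 with the largest moderated statistic among genes meeting those other conditions. Since 0 genes passed, the second form applied, and PRMT5 is also among the 8 lower genes. PRMT5, WDR77, CLC and CTSB were added in advance, and up to 4 members of each list with the smallest p. The text names 2 of these per list, and 4 for the cholesterol and stress response lists. Families silent in blood cells were listed after the leading genes had been seen and before their own values were computed.

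The test of probes was tested on simulated data drawn from the means and spreads of the 29187 probes, with 50 bright probes changed at each size. It recovered 0% of 2-fold, 70% of 4-fold, 98% of 8-fold and 96% of 16-fold changes, with 10 calls among unchanged probes. The list test found a list of 18 genes lowered by 0.3 log2 in 90 of 100 simulated sets, and made any call in 1 of 100 sets without change. These sets drew each gene independently of the others, so both rates leave out lists whose genes vary together. On the real arrays the estimated correlation was 0.087 for the cholesterol list and 0.49 for the glycolysis list.

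Alternatives fixed in advance were no normalization, median centring, an added constant (3.22, the 10th percentile), a filter on dim probes, an intensity trend, robust hyperparameters, array weights, the replicate number as a block, each array left out in turn, the mean over a gene's probes, other set tests and an unmoderated statistic. With an array left out, its group kept 2 arrays. Alternatives added after the data had been seen were a constant of 50, both arrays numbered 3 left out, and the block combined with the dim filter, with and without a trend and robust hyperparameters. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.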

Results

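Gene expression was profiled in NALM6, an established human line of precursor B-cell acute lymphoblastic leukaemia. The cells carried a short hairpin RNA against PRMT5 (sh-PRMT5) or against luciferase (sh-Luc, the control), delivered by transient transfection. Each group had 3 single-colour arrays with 29187 probes. Median intensity was 60.5, 48.9 and 45.0 on sh-Luc arrays 1, 2 and 3, and 52.3, 64.4 and 75.0 on the sh-PRMT5 arrays of the same numbers. The single comparison, sh-PRMT5 against sh-Luc, asked which genes depend on PRMT5 in this leukaemia. The series title places it in the context of leukaemic cell differentiation. The sample titles name no other hairpin against PRMT5 and no rescue. Off-target effects of the hairpin therefore cannot be told apart from PRMT5 loss. All log2 differences below are sh-PRMT5 minus sh-Luc.

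PRMT5, the protein arginine methyltransferase targeted by the hairpin, was lower on each of the 3 sh-PRMT5 arrays. Its deposited intensity was 195 ± 18.6 (SD, n = 3) against 529.6 ± 72.3 (SD, n = 3) in sh-Luc. Single sh-PRMT5 arrays read 214, 193 and 177, and sh-Luc arrays 613, 488 and 487. After normalization the difference was -1.58 on the log2 scale (SE 0.22), leaving 33.5% of the control level (95% confidence interval 23.1 to 48.7%). PRMT5 had the smallest p of the 9410 genes brighter than the median gene, and ranked 18 by p among all 18821 genes. WDR77, its partner in the methylosome, was dim and differed by 0.0049 (SE 0.29), with a sign that turned under median centring (-0.0069). PRMT5 was measured by 1 probe. Its adjusted p from limma with Benjamini-Hochberg was 0.334 over all genes and 0.00212 adjusted over the list alone, a list of 6 genes named for the PRMT5 complex. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 arrays against 3 allow.

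**Figure D1:**
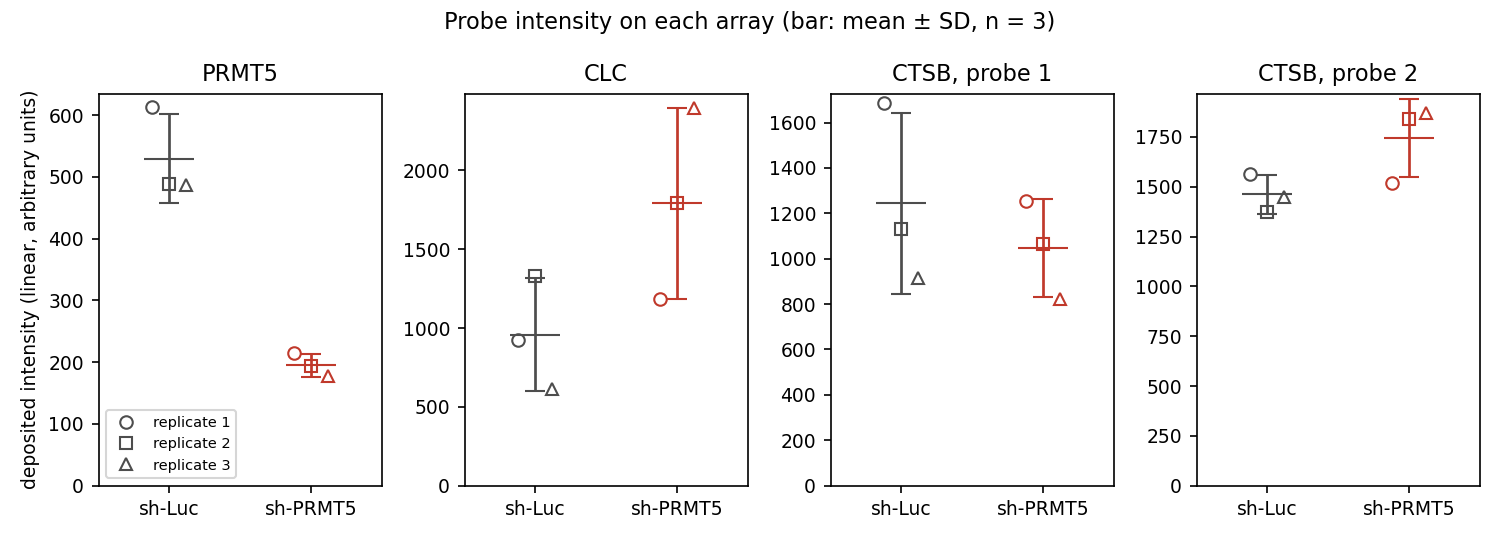
Deposited linear intensity (vertical axes, arbitrary units) of the probes for PRMT5, CLC and CTSB on the 3 sh-Luc and 3 sh-PRMT5 arrays before normalization; open symbols are arrays, horizontal bars means and whiskers 1 SD. PRMT5 lay between 177 and 214 in sh-PRMT5, below every sh-Luc array, while the pair of CTSB probes shifted in opposite directions.

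No gene, PRMT5 included, passed the test over all genes. In limma with Benjamini-Hochberg adjustment, 0 of 29187 probes and 0 of 18821 genes passed an adjusted p of 0.05. The lowest adjusted p among genes was 0.171 (SIAH3, named after its value was seen), a gene near the floor of the array. At an unadjusted p under 0.05 there were 1440 probes, 849 higher and 591 lower, where chance gives 1459. An unmoderated equal-variance statistic with Benjamini-Hochberg adjustment called 1 probe, for WNK3, also near the floor and named after its value was seen. The groups did not overlap in 1894 genes (10.1%, where chance gives 10%), 1023 higher and 871 lower. Simulated 2-fold changes were recovered in 0% of cases, 4-fold changes in 70% and 8-fold changes in 98%. So this test would miss 2-fold changes under the simulated setting. That setting changed 50 probes per size among 29187 and used the spread of the fit without a replicate block. It does not show what other models or a larger share of changed probes would detect.

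The genes that ranked highest among those with separated groups did not pass the test; apart from PRMT5, described above, each had an adjusted p of 0.916 by limma with Benjamini-Hochberg. Among those higher in sh-PRMT5, BMPR1B, a receptor for bone morphogenetic proteins, differed by 0.95 (SE 0.23), with an intensity of 248 ± 64.5 (SD, n = 3) against 109.8 ± 6.74 (SD, n = 3). OPTC, an extracellular matrix protein of the eye, differed by 0.91 (SE 0.22). MSH5, a meiotic recombination protein, differed by 0.83 (SE 0.23). The remaining genes of this kind were FAHD1 (0.79, SE 0.21), ZNRF3 (0.71, SE 0.18), a ubiquitin ligase that restrains Wnt receptors, and the noncoding RNAs LINC01600 (0.81, SE 0.20), CASC2 (0.73, SE 0.21) and ADAMTSL4-AS1 (0.68, SE 0.19). The probes for ZNRF3 disagreed, and their mean differed by -0.36. Beside these, 112 bright members of gene families silent in blood cells (olfactory and taste receptors, keratin-associated proteins, beta-defensins and late cornified envelope proteins) had a median difference of 0.33, and 82 of them were higher.

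Among genes lower in sh-PRMT5, INHBE, an inhibin subunit, differed by -0.82 (SE 0.22) and LDHD, a lactate dehydrogenase of mitochondria, by -0.69 (SE 0.22). OPLAH, an enzyme of the glutathione cycle, differed by -0.63 (SE 0.17), and the zinc finger gene ZBED1 by -0.62 (SE 0.16). EEF1A2, a translation elongation factor, differed by -0.61 (SE 0.17), with 4418 ± 271 (SD, n = 3) in intensity against 6849 ± 729 (SD, n = 3). The tetraspanin TSPAN31 differed by -0.59 (SE 0.17) and RFLNB by -0.57 (SE 0.17). None of these passed the test.

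CLC and CTSB are remembered as genes the study followed up, so their direction here is not independent evidence. CLC, the Charcot-Leyden crystal protein of eosinophils and basophils, had an intensity of 1792 ± 606 (SD, n = 3) in sh-PRMT5 and 957 ± 359 (SD, n = 3) in sh-Luc. Arrays 1, 2 and 3 read 1187, 1793 and 2398 in sh-PRMT5 and 925, 1330 and 615 in sh-Luc, so CLC was higher within each number while the ranges of the groups overlapped. The difference was 0.90 (SE 0.38), with an adjusted p of 0.916 by limma with Benjamini-Hochberg. CTSB, the lysosomal protease cathepsin B, had 2 probes with opposite signs, and the 95% confidence interval of each covered 0. The brighter differed by 0.25 (SE 0.17) and the other by -0.25 (SE 0.30). Under median centring alone the brighter probe differed by -0.058.

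Genes of cholesterol synthesis were lower together. All 18 measured members of a list of 23 were lower in sh-PRMT5 (17 without normalization), with a median difference of -0.27 and a range from -0.43 to -0.010. The members with the smallest p were MVD (-0.29, SE 0.16), PMVK (-0.31, SE 0.18) and MVK (-0.27, SE 0.18), enzymes of the mevalonate pathway, and the sterol isomerase EBP (-0.43, SE 0.25). No member passed the test, over all genes or adjusted over the list alone. As a group the list fell in limma's camera with a preset correlation of 0.01 (p = 0.000557, adjusted p = 0.0156 by Benjamini-Hochberg over 28 lists). The call was lost with an estimated correlation (adjusted p = 0.920 with an estimated correlation) and with fry (adjusted p = 0.742). Over the alternatives tried the adjusted p ran from 6.1e-06 to 0.920. The list's mean, as a deviation from each gene's mean over all arrays, was 0.19, 0.14 and 0.0093 on the sh-Luc arrays and 0.052, -0.055 and -0.34 on the sh-PRMT5 arrays, so the groups overlapped (exact two-sided permutation p = 0.2). The call ended without sh-Luc array 1 (adjusted p = 0.268), without sh-Luc array 2 (0.0978) and without sh-PRMT5 array 3 (0.382, median -0.12, 13 of 18 lower), all from limma's camera with Benjamini-Hochberg. It also ended with array weights (0.0514) and without both arrays numbered 3 (0.0807).

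**Figure D2:**
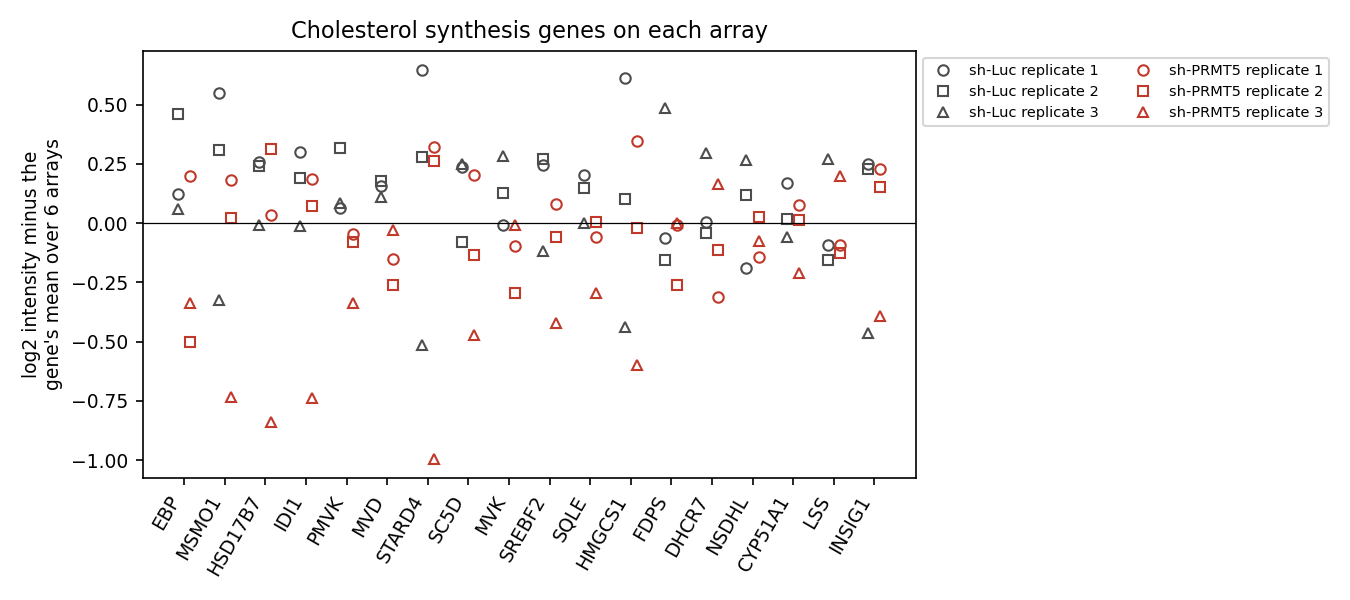
Log2 intensity of the 18 measured cholesterol synthesis genes on each array, as the deviation from the gene's mean over 6 arrays (vertical axis, log2); grey symbols are sh-Luc, red symbols sh-PRMT5 and the shape gives the replicate number. The array sh-PRMT5 replicate 3 had the lowest list mean, -0.34, and the arrays of the groups overlapped for most genes.

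Genes of the integrated stress response, which follow the transcription factor ATF4, were lower in 18 of 20 measured members, with a median of -0.14. Examples were TRIB3 (-0.44, SE 0.22), DDIT3 (-0.43, SE 0.30), STC2 (-0.40, SE 0.18) and CEBPG (-0.37, SE 0.23), and 0 members passed the test. The list itself did not pass in limma's camera (adjusted p = 0.171 by Benjamini-Hochberg). It passed under 7 of 21 alternatives, such as no normalization and leaving out dim probes, and the adjusted p over all of them ran from 2.3e-05 to 0.920. The list's mean, as a deviation from each gene's mean over all arrays, overlapped between the groups (exact two-sided permutation p = 0.5). It was -0.054, 0.022 and 0.26 on sh-Luc arrays 1, 2 and 3 and 0.029, -0.23 and -0.024 on the sh-PRMT5 arrays, so for number 1 it was higher in sh-PRMT5.

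None of the other 26 lists passed limma's camera, with adjusted p from 0.410 to 0.969 by Benjamini-Hochberg, and in each of them 0 members passed the test over all genes. The PRMT5 complex list had 4 of 6 members lower and a median of -0.33, with RIOK1, an adaptor of PRMT5, at -0.54 (SE 0.75). The list was PRMT5, WDR77, CLNS1A, RIOK1, COPRS and MTAP, so its lower direction was partly set by the target of the hairpin itself. The other arginine methyltransferases had a median of 0.049, with 5 of 8 higher; PRMT2 differed by -0.26 (SE 0.26) and PRMT9 by -0.26 (SE 0.31).

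Genes of B-cell identity did not pass as a group. Precursor B-cell genes were higher in 15 of 25 members (median 0.064), and most of them were dim on this array. SOX4 differed by 0.59 (SE 0.24) and the recombinase gene RAG2 by 1.18 (SE 0.62), with a mean intensity of 2.72 in sh-Luc and 6.57 in sh-PRMT5. Mature B-cell and plasma-cell genes were split evenly, 10 of 20 higher, with a median of -0.014. TNFRSF17, a plasma-cell receptor, differed by 0.69 (SE 0.35) and the memory B-cell marker CD27 by 0.47 (SE 0.25), both dim.

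Markers of other blood lineages had higher medians without passing after quantile normalization over all genes. Most were dim, with 9 of 23 myeloid, 2 of 9 eosinophil and basophil and 4 of 18 T-cell and NK-cell markers bright. Of the erythroid and megakaryocyte markers 9 of 11 were bright. Myeloid markers were higher in 15 of 23 members (median 0.31), and the list's mean per array did not overlap between the groups (exact two-sided permutation p = 0.1, the smallest possible). They passed as higher after median centring alone (median 0.28, adjusted p = 0.0412 by limma's camera with Benjamini-Hochberg), where the median gene was lower. Members pointed both ways, with LYZ (lysozyme) at -0.69 (SE 0.24) and TYROBP, an adaptor of myeloid receptors, at 0.44 (SE 0.16). Eosinophil and basophil markers were higher in 6 of 9 members (median 0.17), where PRG2, the eosinophil major basic protein, differed by -0.74 (SE 0.27), against the direction of CLC. T-cell and NK-cell markers were higher in 10 of 18 members (median 0.17), with CD8A at 0.70 (SE 0.31) and NCAM1 at 0.67 (SE 0.34). They passed as higher in limma's camera with dim probes left out, where few members remained. Erythroid and megakaryocyte markers had a median of 0.012, with 6 of 11 higher, ITGA2B at 0.60 (SE 0.23) and HBB at -0.36 (SE 0.21). Fibroblast and epithelial markers had a median of 0.045, with 7 of 13 higher. Among them FAP differed by 1.18 (SE 0.44) and COL1A2 by 0.76 (SE 0.21), both dim, and the mean over the COL1A2 probes was -0.13. Beside these markers, the families silent in blood cells described above had a median of 0.33.

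Neither cell-cycle list passed after quantile normalization. G1/S and replication genes were higher in 19 of 26 members (median 0.084), with CCNE2, a cyclin of S-phase entry, at 0.39 (SE 0.19) and SLBP at -0.30 (SE 0.26). G2/M and mitosis genes were lower in 20 of 26 (median -0.070), with HMMR at -0.53 (SE 0.31) and the mitotic kinesin KIF20A at -0.34 (SE 0.21). They passed as lower in limma's camera with Benjamini-Hochberg without normalization (adjusted p = 0.00798, median -0.032) and after median centring alone (adjusted p = 0.00408, median -0.34). After median centring the median gene was also lower (-0.17), and common reference genes passed as lower too (median -0.30). With an estimated correlation, after quantile normalization, camera gave G2/M genes an adjusted p of 0.977. Their mean deviation was 0.093, 0.044 and 0.025 on the sh-Luc arrays and 0.042, 0.021 and -0.22 on the sh-PRMT5 arrays (exact two-sided permutation p = 0.2). CDK inhibitors and cyclin D genes had a median of -0.0063, with 6 of 12 lower, RB1 at -0.26 (SE 0.20) and CCND2 at 0.23 (SE 0.31). Targets of p53 were lower in 17 of 24 members (median -0.098), with EDA2R at 0.84 (SE 0.35), SPATA18 at 0.97 (SE 0.41) and the proapoptotic gene BBC3 at -0.39 (SE 0.17). Apoptosis regulators were lower in 12 of 21 (median -0.014), with BIK at 0.71 (SE 0.35).

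Genes for Sm proteins and spliceosome assembly, whose products include PRMT5 substrates, had a median of 0.037, with 14 of 22 higher. SRSF2 differed by 0.27 (SE 0.19) and SNRPE by -0.40 (SE 0.41). Interferon-stimulated genes were lower in 14 of 25 members (median -0.16), with RSAD2 at -0.79 (SE 0.29) and OAS2 at 0.49 (SE 0.23). NF-kB and inflammatory genes had a median of 0.029, with 11 of 21 higher; TRAF1 differed by 1.86 (SE 0.45) at a mean intensity of 2.02 in sh-Luc, and NFKB2 by -0.61 (SE 0.25). Unfolded protein and heat shock genes were lower in 13 of 21 (median -0.023), with HSPA8 at 0.24 (SE 0.18) and SEL1L at -0.32 (SE 0.27). DNA damage repair genes were lower in 12 of 20 (median -0.027), with XRCC2 at -0.74 (SE 0.33) and BRIP1 at 0.35 (SE 0.22).

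Metabolic and growth genes had medians near 0 after quantile normalization, the setting of the values that follow unless stated. After median centring alone the MYC, ribosomal protein, oxidative phosphorylation, glycolysis, lysosome and reference lists passed as lower in limma's camera. Their medians there were -0.29, -0.31, -0.30, -0.29, -0.27 and -0.30, where the median gene was also lower (-0.17). MYC and ribosome biogenesis genes had a median of 0.0098, with 13 of 22 higher, PES1 at -0.44 (SE 0.23) and MYCN, near the floor, at -1.43 (SE 0.63). Cytosolic ribosomal protein genes were lower in 13 of 23 (median -0.028), with RPL3 (-1.76, SE 0.85) and RPS15 (-0.64, SE 0.45) measured by dim probes only. Oxidative phosphorylation genes were lower in 12 of 22 (median -0.0080), with ATP5F1A at 0.31 (SE 0.32) and UQCRB, near the floor, at -0.48 (SE 0.64). Glycolysis and hypoxia genes were higher in 12 of 23 (median 6.2e-07), with the angiogenic factor VEGFA at -0.49 (SE 0.19) and ENO2 at 0.53 (SE 0.30). Lysosome and cathepsin genes were higher in 13 of 22 (median 0.018), with CTSS at -0.49 (SE 0.31). Common reference genes were lower in 6 of 11 (median -0.031, turning to 0.0048 without normalization), with HPRT1 at -0.24 (SE 0.17) and SDHA at -0.13 (SE 0.22). Replication-dependent histone genes, which lack poly(A) tails and so report on the amplification of RNA, had 7 of 14 higher and a median of 0.0030, with H2AC4 at -1.02 (SE 0.73) and H1-5 at -0.17 (SE 0.24).

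The sign of the median, the mean and the test differed in 7 of the 28 lists, those for other arginine methyltransferases, mature B cells, MYC and ribosome biogenesis, oxidative phosphorylation, glycolysis, NF-kB and histones. Directions of genes and lists also moved with the scaling. So did the median gene, which differed by -0.018 after quantile normalization, by 0.14 without normalization and by -0.17 after median centring. List medians kept their sign under both scalings in 11 of 28 lists, those for cholesterol synthesis, the PRMT5 complex, the integrated stress response, unfolded protein, G2/M, NF-kB, precursor B-cell, myeloid, eosinophil, T-cell and fibroblast genes. In the other 17 they turned under a scaling. At an unadjusted p under 0.05, the split of 849 higher to 591 lower became 1733 to 148 without normalization.

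**Figure D3:**
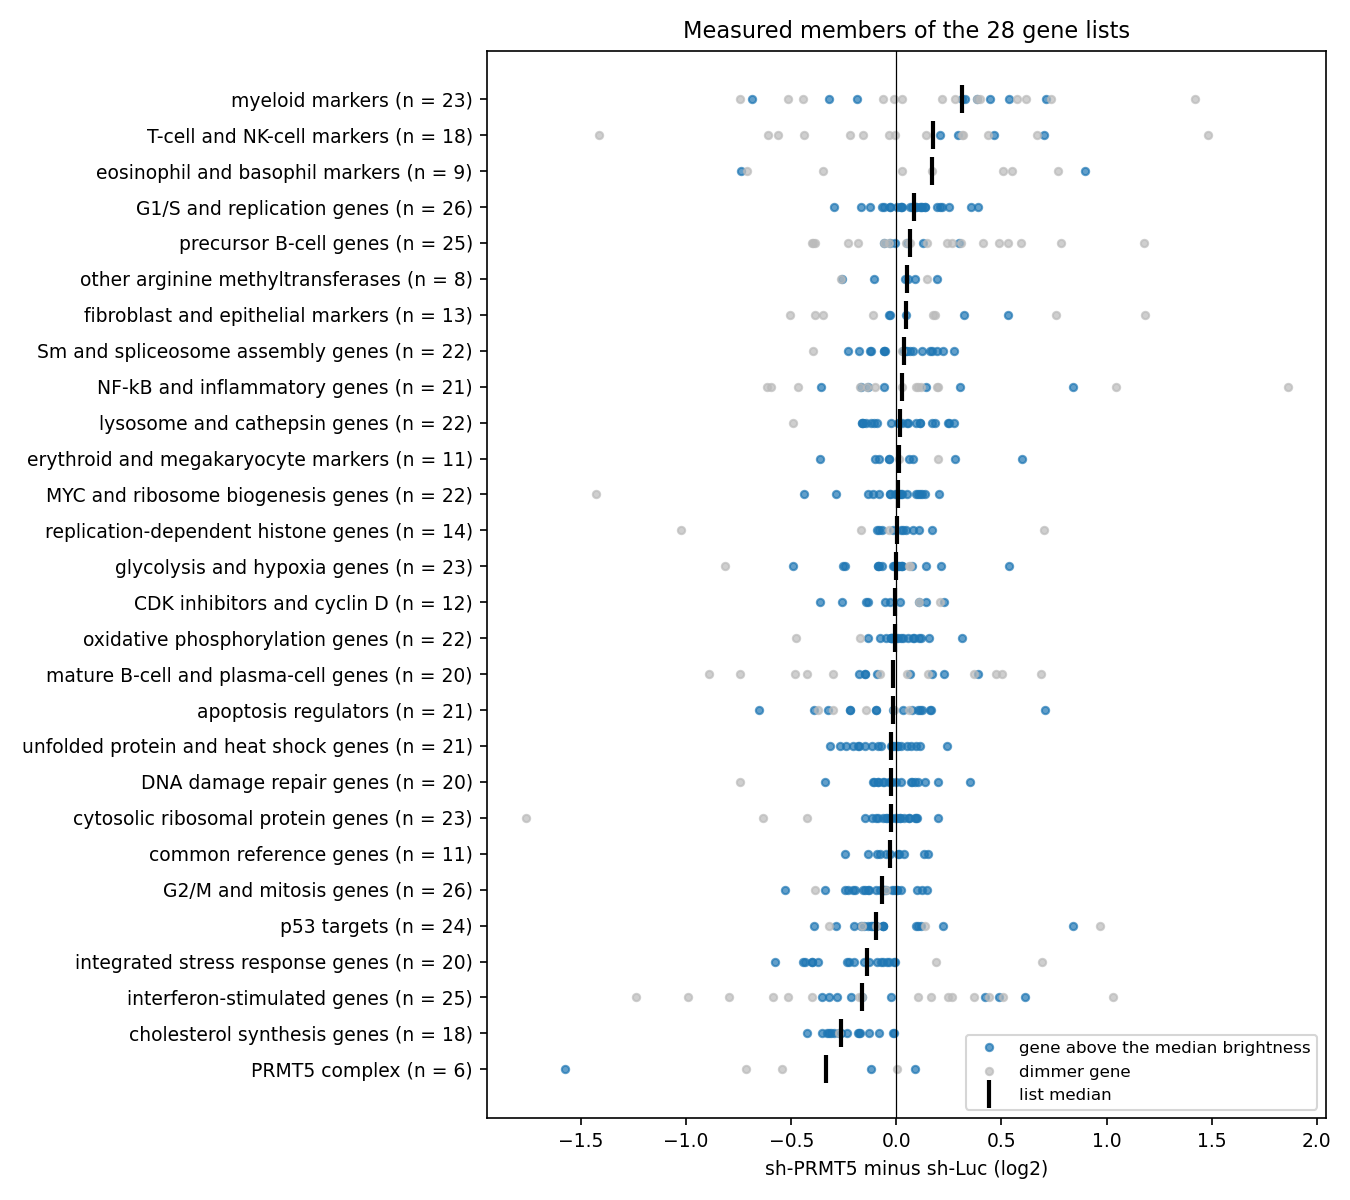
Log2 difference, sh-PRMT5 minus sh-Luc (horizontal axis), of every measured member of the 28 gene lists (rows, with the number of measured genes); blue points are genes brighter than the median gene, grey points dimmer genes and black bars list medians. All 18 cholesterol synthesis genes lay below 0 (17 without normalization), PRMT5 was the lowest bright point at -1.58, and directions near 0 turned with the scaling.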

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

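A constant of 50, leaving out both arrays numbered 3 and the block combined with other settings were chosen after the data had been seen. PRMT5 kept its direction under all 18 alternatives, between -1.75 and -1.35, with adjusted p from 0.0226 to 0.911 in limma with Benjamini-Hochberg. It passed (-1.58, 1 probe and 1 gene, adjusted p = 0.0226 over probes) only with the replicate block, dim probes left out, trend and robust together, a setting with fewer probes to adjust over. Counts of probes and genes stayed at 0 otherwise, except 1 probe for the unmoderated statistic and 0 to 1 with an array left out. Those single calls were SLC26A6 without sh-Luc array 1, PCDHB6 without sh-Luc array 2 and KAT2B without sh-Luc array 3, named after their values were seen. At unadjusted p under 0.05, array weights gave 3586 probes and the dim filter 726, against 1440. The count of lists that passed, 1, became 5 without normalization, 12 after median centring, 3 with dim probes left out (also with the block added, and with trend and robust added), and 2 with an intensity trend or a constant of 50. It was 0 with array weights, an estimated correlation and fry, and 0 to 1 with arrays left out. Beside cholesterol and the integrated stress response, the lists that passed as lower without normalization were PRMT5 complex (which holds the hairpin's target), G2/M and unfolded protein (adjusted p = 0.0235, 0.00798 and 0.0463 by limma's camera with Benjamini-Hochberg). After median centring G2/M, unfolded protein, MYC, ribosomal protein, oxidative phosphorylation, glycolysis, lysosome, DNA repair and reference genes passed as lower and myeloid markers as higher. T-cell and NK-cell markers passed with dim probes left out, where 5 members remained (median 0.46, adjusted p = 0.00811 by limma with Benjamini-Hochberg). The cholesterol list kept its direction under all 21 alternatives. It lost its call with array weights (median -0.18), an estimated correlation and fry, and its median ran from -0.33 to -0.12 with arrays left out. The median gene lay at -0.018, moved to 0.14 without normalization and to -0.17 after median centring. Relative to it the cholesterol median was -0.25, and -0.34 under either scaling. These last values had to be equal, since median centring moves all genes of an array by the same amount, so they count as 1 check. The block alone left the counts at 0 probes, 0 genes and 1 list (cholesterol, adjusted p = 0.00262). The block was not taken as a pairing, since deviations of equal numbers correlated at 0.060, 0.0091 and 0.16 over all probes and the labels do not say what a number marks. Over bright probes they correlated at 0.31, 0.13 and 0.49, so the decision depends on the probes used. There sh-Luc array 2 correlated more with sh-PRMT5 array 1 (0.30) than with its own number, while the arrays numbered 3 correlated best with each other. Dim probes near background limit the precision, with a median SE of 0.40 against 0.22 for bright genes. The cause was not tested for the changes above and the reversals that follow.

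The test direction of lists without a call as reported turned as follows, with list medians. Without normalization these were erythroid 0.079, G1/S 0.11, Sm and spliceosome 0.063, oxidative phosphorylation 0.012, lysosome 0.039 and NF-kB 0.32. After median centring they were -0.23, -0.20, -0.24, -0.30, -0.27 and 0.0079 in the same order. Of these, oxidative phosphorylation and lysosome genes passed as lower after median centring (adjusted p = 0.0202 and 0.0224 by limma's camera with Benjamini-Hochberg), a setting in which the median gene was also lower. With dim probes left out, alone or with the block, they were MYC 0.013, ribosomal protein -0.0032, DNA repair -0.027, NF-kB 0.040 and histone 0.027. Array weights turned erythroid -0.021, oxidative phosphorylation 0.020, glycolysis 0.032 and DNA repair 0.022. Mature B-cell genes turned with the trend (-0.014) and the constant of 50 (0.0037), lysosome with the mean over probes (0.0036) and NF-kB with fry (0.029). With arrays left out, ranges of medians for lists that turned were -0.15 to 0.11 for other arginine methyltransferases, -0.068 to 0.10 for mature B-cell genes, 0.040 to 0.43 for eosinophil, 0.064 to 0.31 for T-cell and -0.11 to 0.13 for erythroid markers. They were -0.032 to 0.16 for G1/S, -0.039 to 0.044 for CDK inhibitors, -0.013 to 0.053 for Sm and spliceosome, -0.12 to 0.076 for unfolded protein and -0.069 to 0.10 for MYC genes. The rest were -0.0095 to 0.014 for oxidative phosphorylation, -0.15 to 0.14 for glycolysis, -0.018 to 0.040 for lysosome, -0.094 to 0.044 for DNA repair, -0.079 to 0.087 for NF-kB and -0.083 to 0.043 for histone genes. Among named genes, PRMT9 (0.0035), SNRPE (0.067) and H1-5 (0.23) turned without normalization. WDR77 (-0.0069), CTSB (-0.058), CCND2 (-0.092), SRSF2 (-0.032) and HSPA8 (-0.088) turned after median centring. SNRPE turned with array weights (0.11), WDR77 with the constant of 50 (-0.0066), and ZNRF3 (-0.36) and COL1A2 (-0.13) with the mean over probes. With arrays left out WDR77 ran from -0.15 to 0.27, PRMT9 from -0.54 to 0.032, ATP5F1A from -0.046 to 0.52 and H1-5 from -0.31 to 0.050.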

Other observations

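The comparison of arrays by number, its restriction to bright genes, and the tests of the cholesterol list other than the splits were chosen after the results had been seen.

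The arrays numbered 3, 1 of each hairpin, stood apart from the other 4. With the hairpin in the limma model, 824 of 9410 bright genes rose and 995 fell on the arrays numbered 3 against the others (Benjamini-Hochberg adjusted p under 0.05), and 0 did for number 1 or number 2. Those counts of 0 say little, since the arrays numbered 3 lie in the comparison group there and add to its spread. For number 2, 27 of the 9410 bright genes had an unadjusted p under 0.05 by limma. On the arrays numbered 3, EGR1, an immediate early transcription factor, rose by 4.63 on the log2 scale (SE 0.19, adjusted p = 0.000122 by limma with Benjamini-Hochberg). EGFL7 rose by 2.04 (SE 0.12), the transcriptional repressor KLF3 by 2.23 (SE 0.15) and the creatine transporter SLC6A8 by 1.96 (SE 0.13). CHAC1 (2.51, SE 0.18), SESN2 (1.39, SE 0.14) and DDIT4 (1.45, SE 0.14) were also higher, but the integrated stress response list, which holds CHAC1 and SESN2, did not pass for number 3 (9 of 20 higher, median -0.060, adjusted p = 0.795 by limma's camera with Benjamini-Hochberg). SAT1, of polyamine breakdown, fell by 1.47 (SE 0.13), the immunoproteasome gene PSMB9 fell by 1.55 (SE 0.14) and MANF, a protein of the endoplasmic reticulum, fell by 1.96 (SE 0.21). These genes were named after their values were seen.

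Over all 18821 genes, dim ones included, 0 genes passed for number 3 and 1 for number 1, and EGR1 had an adjusted p of 0.102 in limma with Benjamini-Hochberg. At an unadjusted p under 0.05 there were 3529 genes for number 3, 851 for number 1 and 531 for number 2, where chance gives 941. Glycolysis and hypoxia genes were higher in 21 of 23 members on the arrays numbered 3 (median 0.50). The list passed limma's camera at the preset correlation (adjusted p = 1.5e-05 by Benjamini-Hochberg), and the call was lost with an estimated correlation (adjusted p = 0.753 with an estimated correlation). HK2 differed by 1.37 (SE 0.20) and PDK1 by 0.94 (SE 0.20). Unfolded protein and heat shock genes were lower (median -0.37, adjusted p = 0.00924 by the same test, and 0.753 with an estimated correlation). G1/S genes were higher (median 0.33, adjusted p = 0.0243 by the same test, and 0.829 with an estimated correlation). For number 1 the lists for glycolysis (2 of 23 higher, median -0.30) and G1/S (median -0.20) passed in the opposite direction (adjusted p = 0.0219 each by limma's camera with Benjamini-Hochberg, and 0.766 with an estimated correlation), and 0 lists passed for number 2. The arrays numbered 3 are part of the comparison group for numbers 1 and 2, so the contrasts of the 3 numbers are not independent of each other. The labels do not say what a number stands for, and no explanation was tested.

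Gene families silent in blood cells were higher in sh-PRMT5, and were listed after the leading genes, OPTC of the eye among them, had been seen. A candidate explanation is more non-specific signal on the sh-PRMT5 arrays. Members of 5 families silent in blood cells and bright on the array (112 genes) had a median difference of 0.33, at percentile 100 of 10000 random lists matched on mean expression, whose 5th to 95th percentiles ran from -0.090 to -0.0072. The median kept its sign without normalization (0.53) and after median centring (0.22). Of the 112, 25 were separated upward (22.3%, where chance gives 5% of independent genes) and 5 downward. Members of these families may vary together, and the matched lists hold unrelated genes. So neither the percentile nor the share can exclude an effect of single arrays. The exact two-sided permutation p of the families' mean per array was 0.1, the smallest possible. That mean, as a deviation, was -0.062, -0.11 and -0.23 on sh-Luc arrays 1, 2 and 3. On the sh-PRMT5 arrays it was 0.0072, 0.11 and 0.28, so the gap was widest for number 3 and narrow for number 1. Array medians before normalization (log2) were 5.92, 5.61 and 5.49 in sh-Luc and 5.71, 6.01 and 6.23 in sh-PRMT5. The dimmest array had the lowest family mean and the brightest the highest, so a dependence on array brightness is not excluded. For number 1 the sh-Luc array was brighter, yet its family mean was lower. An effect of PRMT5 loss on silent genes was not tested and stays open.

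Lower cholesterol synthesis genes after PRMT5 knockdown are a hypothesis with limits. A general shift of bright genes was argued against, since the list median of -0.27 lay at percentile 0 of 10000 lists matched on mean expression (5th percentile -0.062). Without the arrays numbered 3 the list stayed lower, with a median of -0.18, 17 of 18 members lower and a percentile of 0. The matched lists hold unrelated genes, so for genes that vary together this percentile cannot exclude an effect of single arrays. That test replaced one of passing or failing the list (adjusted p = 0.0807 by limma's camera with Benjamini-Hochberg), which had decided nothing. Without sh-PRMT5 array 3 alone the median was -0.12 and 13 of 18 members were lower. Whether these genes vary as 1 unit between arrays whatever the hairpin stays open. The overlap of the list's means between groups goes with that explanation (exact two-sided permutation p = 0.2, a test that ignores the replicate number). With the hairpin in the model, the list was lower on the arrays numbered 3 (median -0.21, 6 of 18 members higher). It was higher on those numbered 1 (median 0.20, 13 of 18) and 2 (median 0.084, 11 of 18), and passed limma's camera for none of the 3 numbers. A split of both arrays numbered 3 and sh-PRMT5 array 2 against the rest also called this list. A response to PRMT5 loss stays open as well: within each of the 3 numbers the list mean was lower in sh-PRMT5, with 14, 16 and 17 of 18 members lower, too few numbers to decide.

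Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. For probes past the test the real value was 0 and the highest other 1, and for genes 0 and 7; a real count of 0 is reached by any split, so these rows test nothing. For probes at an unadjusted p under 0.05 it was 1440 against 2997 (4 of 10 splits as large), for lists 1 against 4 (6 of 10), and for the cholesterol list's camera p 0.000557 against 0.00344 (1 of 10). The split with 2997 probes set both arrays numbered 3 and sh-PRMT5 array 2 against the rest, but the other 3 splits that kept the arrays numbered 3 together gave 1762, 1247 and 1051. With the number as a block the real comparison had 1689 such probes.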
